A study of Homo sapiens with 4 samples.

How the data were processed

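RNA from 4 cell cultures was hybridised to Affymetrix 1-colour arrays with 54675 probe sets. Per the labels, the cells were stably transduced after antibiotic selection, total RNA was extracted with a column kit, and biotin-labelled cRNA was prepared from it. The deposited values are intensities on a linear scale, from 2.462 to 15500, never negative. Per the submitters' processing notes, the values were made with MAS5; the software version, scaling target and detection calls are not given in the sources used here. The scale (linear) was settled from the values. The normalization was not: the percentiles of the 4 arrays lay closer together than MAS5 scaling alone usually gives, with 75th percentiles of 85.21, 86.84, 86.6 and 88.18, and dim probe sets scattered little between arrays of a line (SD of the log2 ratio 0.2384 in A549 and 0.2371 in NCI-H358 below the filter, against 0.1934 and 0.2047 above it). A further step on the deposited values is therefore possible, and it could compress differences of dim genes; scanner files were not used here. The arrays of a line held 1 probe set with the same value in A549 and 0 in NCI-H358, so they were treated as separate measurements.

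Group membership was taken from the sample labels, with 1 array in each of the 4 groups, so no replicate check within a group could be made. Values were floored at 16.14, the 50th percentile of all values, and log2 was then taken. A gene was measured in a cell line when its signal was at least 27, the 60th percentile of all values, on at least 1 of the 2 arrays. The platform annotation gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721, and 62 control probe sets were left out. Of the single-gene probe sets, 99.9% matched a current gene record of the RefSeq annotation by Entrez ID, and the update changed 0 symbols. Each of 19775 genes was represented by its single-gene probe set with the highest mean log2 signal; probe sets with several or no symbols named no gene. The ferritin heavy chain gene and other genes without a single-gene probe set were not analysed here.

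Within a cell line, genes were counted by a rule of size, at least 2-fold, with no p-value. The SD of the log2 ratio between probe sets of the same gene, from 5117 genes in A549 and 5150 in NCI-H358, served as the gauge of error. Between vectors, a fold whose dimmer side was floored is given as at least that fold; between cell lines, arrays of the dimmer line under the filter were raised to it and the fold is given as at least that. The shared difference and the difference between cell lines were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, terms for cell line and vector, Benjamini-Hochberg adjusted p of 0.05, 12273 genes). The fit left 1 residual degree of freedom per gene, with a prior of 3.5, and its error term was the difference between the lines in their response, so a gene that responded in 1 line only had a large error. In 20 simulations of the shared comparison with 200 changed genes it called 88.4% of those changed by log2 1 and 14.7 unchanged genes on average. Overlaps were set against the product of the list sizes and 10000 shuffles within 20 bins of mean signal. For gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins, a description of these arrays and not a test across cultures. In a simulation on the A549 arrays, 97.0% of 25-gene lists shifted by log2 0.15 lay above the central 95% of random lists. Of unshifted lists, 5.0% lay outside it. The observed A549 list medians outside that range were all smaller in size than 0.15, so the 97.0% does not describe shifts like theirs. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

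Sample groups, tests, 27 gene lists with 735 distinct genes (596 measured), alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names CHST11; per cell line the 10 highest and 10 lowest genes by the smallest ratio among all measured probe sets of a gene, where these had the same sign; for the shared difference the 10 highest and 10 lowest by the smaller ratio of both lines; for the cell line difference the 10 highest and 10 lowest by fitted log2 difference; the 2 highest and 2 lowest members of each list by the mean of both lines; and CP, TFRC, FTL, SLC40A1, CDH1, VIM, CD44 and VCAN whatever their values. Of the 185 genes this gave, the text prints those with a described function or a part in a comparison. Exceptions are named as chosen after their values were seen. The list of 67 genes with long mRNAs was written from general knowledge after the A549 ratios of 11 of them had been seen, so values without those 11 are also given. The zinc finger, histone and mitochondrial genome groups were chosen after seeing the data too.

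Alternatives were quantile normalization, median centring and cyclic loess normalization of the arrays, a floor at the 25th percentile, no floor (log2 of the value plus 1), the median of a gene's probe sets, a filter at the 75th percentile, no filter, a 1.5-fold rule, eBayes with a trend and a fit without the block. The counts and the correlation were also computed without the long mRNA and mitochondrial genes, and the overlaps without CHST11, choices made after seeing the data.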

Results

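Gene expression was measured on 4 Affymetrix arrays in A549, a human lung adenocarcinoma cell line, and NCI-H358, a human bronchioloalveolar carcinoma cell line, each stably transduced with an empty vector or with a vector for CHST11. CHST11 is a Golgi sulfotransferase that adds sulfate to chondroitin chains. The groups were A549 empty vector, A549 CHST11, NCI-H358 empty vector and NCI-H358 CHST11, with 1 array in each, so values within a cell line had no replicate and no p-value, and the number of arrays limited the precision. The median deposited signals were 16.31, 16.07, 16.29 and 15.9 in that order, and 11450 genes in A549 and 11395 in NCI-H358 passed the signal filter. The log2 signals of all probe sets correlated with r = 0.9961 between the A549 arrays, 0.996 between the NCI-H358 arrays and 0.9376 to 0.9387 between the lines. As a gauge of error, log2 ratios of different probe sets of the same gene had an SD of 0.158 in A549 and 0.173 in NCI-H358. This gauge covered measurement scatter on the arrays and not the spread between cultures.

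The first comparison asked whether the arrays showed the CHST11 vector. In A549, the CHST11 probe set 219634_at had a signal of 129 with the empty vector and 343.5 with the CHST11 vector, a 2.66-fold difference. In NCI-H358 the same probe set had signals of 220.1 and 1058, a 4.8-fold difference. The other 2 CHST11 probe sets lay close to their empty vector level, with log2 ratios of 0.11 and -0.05 for 226368_at and of -0.16 and 0.14 for 226372_at in A549 and NCI-H358. The difference at 219634_at, log2 1.41 and 2.26, was several times the spread between probe sets of a gene. The CHST11 difference therefore rested on 1 of its 3 probe sets.

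**Figure D1:**
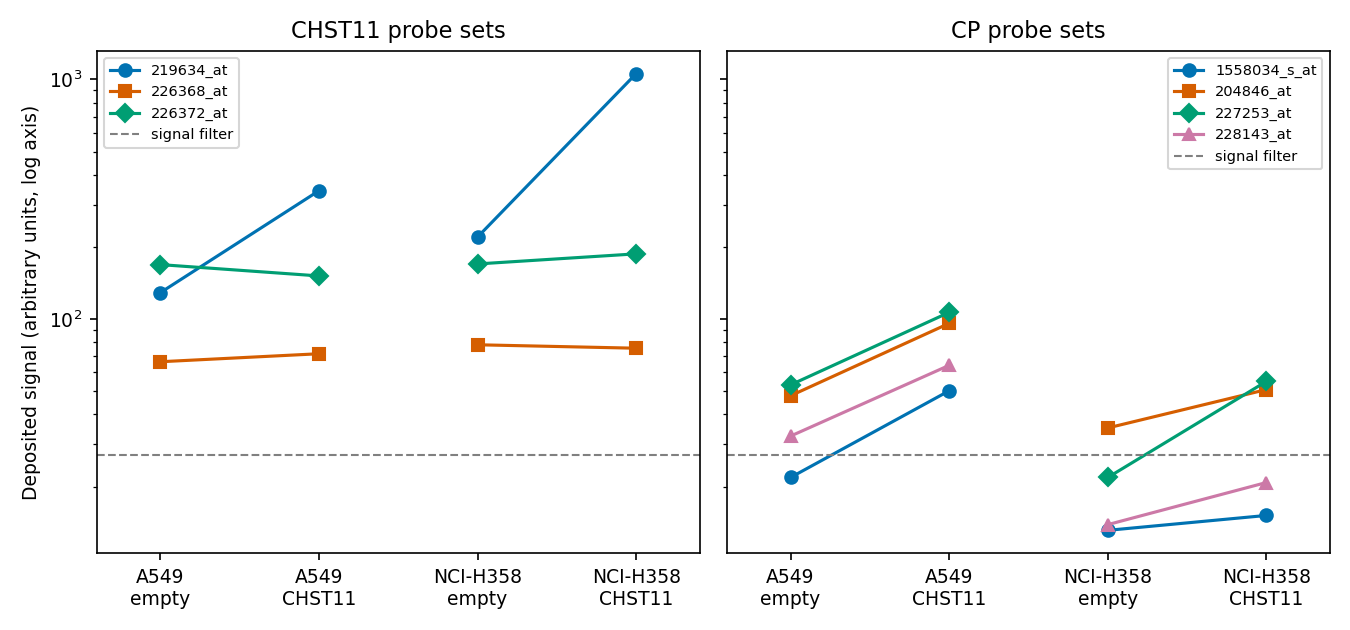
Deposited signal of each probe set annotated to CHST11 (left) and CP (right) on a log axis, with 1 point per array and lines joining the empty vector and CHST11 arrays of a cell line; the dashed line is the signal filter at 27. The CHST11 probe set 219634_at went from 129 to 343.5 in A549 and from 220.1 to 1058 in NCI-H358, while the other 2 stayed near their level.

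In A549, 13 genes differed at least 2-fold between the vectors, 4 higher and 9 lower with CHST11. Beside CHST11, the higher genes were BIK, a pro-apoptotic member of the BCL family (signal 26.75 and 73.03, 2.73-fold), C1R, a serine protease of the complement pathway (71.35 and 156.4, 2.19-fold), and CP, ceruloplasmin, the copper-carrying ferroxidase of plasma (47.89 and 96.01, 2.0-fold). The lowest was CEACAM6, a cell surface adhesion glycoprotein, at 777.7 with the empty vector and 214.3 with CHST11, which was 3.63-fold lower. Also lower were SPINK6, a serine protease inhibitor (2.92-fold), CEMIP, a hyaluronan-binding protein (2.58-fold), COL4A4, a basement membrane collagen chain (at least 2.88-fold), CST1, a cystatin (at least 2.16-fold), and C4BPB, a chain of a complement regulator (2.0-fold). GDA, guanine deaminase, was 2.35-fold lower, CA2, a carbonic anhydrase, 2.07-fold lower, and SYNE2, a nuclear envelope protein, 2.08-fold lower.

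Just under the 2-fold size in A549 stood HS3ST6, a heparan sulfate sulfotransferase (log2 0.99, signal 20.89 and 41.61), SLC25A45, a mitochondrial carrier (0.89), LINC02985, a noncoding RNA (0.86), ND2, a respiratory chain subunit encoded in the mitochondrial genome (0.86), PTPRO, a receptor tyrosine phosphatase (0.85), HLA-DMB, a peptide loading factor of antigen presentation (0.85), and FOXA3, a forkhead transcription factor (0.85). PAGE5, a cancer testis antigen, had a log2 ratio of -0.91. All 4 CP probe sets above the filter in A549 lay between log2 0.98 and 1.20, and the other CEACAM6 probe set lay at -1.71. At 1.5-fold, 138 genes differed, 56 higher and 82 lower, and in 27 of the 34 with at least 2 measured probe sets all probe sets had the same sign. Genes with long mRNAs lay low in this pair of arrays: of 62 measured genes of such a list, 61 were below 0, the median log2 ratio was -0.474, and 23 were at least 1.5-fold lower, among them SYNE2. The 7 measured genes of the mitochondrial genome, ND2 included, lay high, with a median of 0.73.

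In NCI-H358, 6 genes were at least 2-fold higher with CHST11 and 0 were at least 2-fold lower, a count by size with no test behind it. The 0 depended on the floor: DBNDD1, with signals of 27.69 and 10.13, was bounded at log2 -0.78 by it and had -1.451 with the floor at the 25th percentile, so that 1 gene was lower under that floor and also with no floor. Beside CHST11 they were ABCA3, a lipid transporter of surfactant-producing alveolar cells (signal 18.59 and 37.84, 2.04-fold), the noncoding RNA LINC01088 (56.01 and 114.8, 2.05-fold), and ZNF320, GPM6A and DNAH5. ZNF320, a zinc finger protein, had a ratio of 2.7-fold, GPM6A, a neuronal membrane glycoprotein, at least 2.4-fold and DNAH5, a ciliary dynein chain, 2.06-fold. These last 3 were named after their values were seen, and their other measured probe set lay at log2 0.41, -0.27 and 0.15. The next highest were C1orf210 (log2 1.0), ATP8A1, a phospholipid flippase (0.97, signal 47.59 and 93.33), ZNF682 (0.94), RNASE1, a secreted ribonuclease (0.91), AKR1B10, an aldo-keto reductase (at least 0.89), ANGPT1, an angiopoietin (at least 0.88), H2BC9, a histone gene (0.85), and NHLRC2 (0.85).

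The genes lowest in NCI-H358 with CHST11 were CCDC18-AS1, an antisense RNA (log2 -0.98), and CYP1A1, the cytochrome induced through the aryl hydrocarbon receptor (-0.96, signal 107 and 54.95). MMP9, a gelatinase, had signals of 130.2 and 76.17 (log2 -0.77). Also low were SLC22A17, a lipocalin receptor (-0.83), MILIP, a noncoding RNA (-0.80), ADRA2B, an adrenergic receptor (-0.77), and FMNL1, a formin (-0.74). At 1.5-fold, 133 genes differed, 102 higher and 31 lower, and in 21 of the 30 with at least 2 measured probe sets all probe sets had the same sign. The long mRNA list lay above 0 in this line, with a median of 0.127 and 47 of 60 genes above 0, and the mitochondrial genome genes had a median of -0.14.

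**Figure D2:**
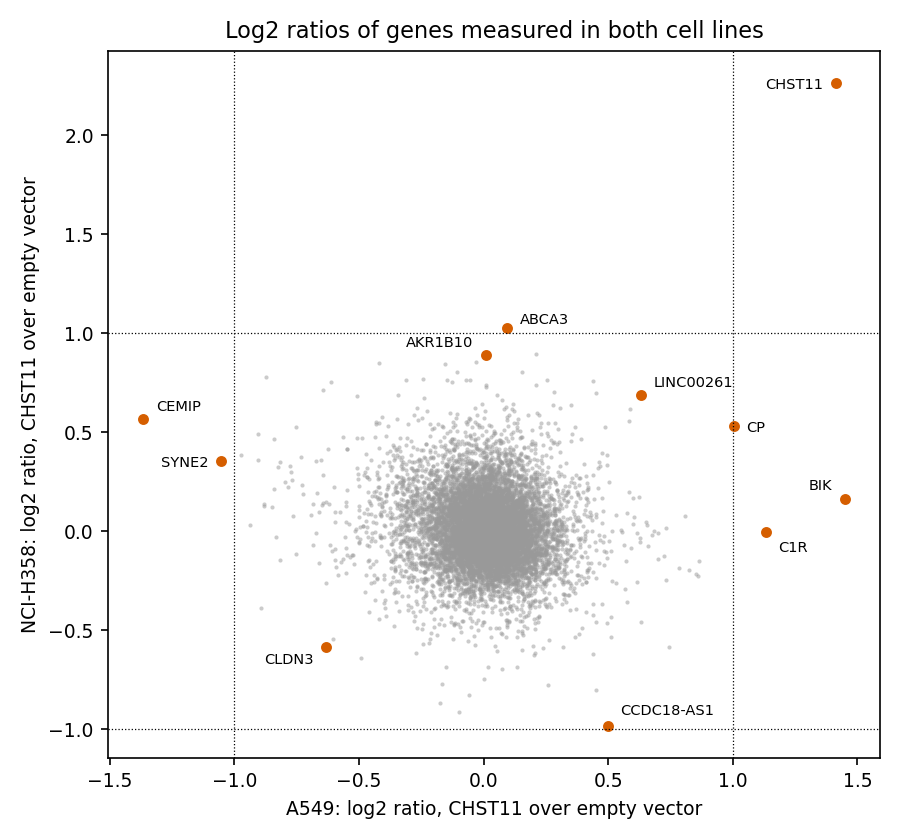
Log2 ratio of CHST11 over empty vector for each of 10572 genes measured in both cell lines, A549 on the x axis and NCI-H358 on the y axis; dotted lines mark 2-fold, and orange points are named genes. By the probe set representing each gene, CHST11, at 1.41 and 2.26, was the only gene at least 2-fold higher in both lines. The cloud of genes had no upward slope (r = -0.091).

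Treating the 2 cell lines as replicates of the vector contrast, CHST11 was the leading shared gene, with a fitted log2 difference of 1.84 (SE 0.218). CP was higher in both lines (log2 1.0 in A549 and 0.53 in NCI-H358, fitted 0.77, SE 0.141). These values are of the probe set that represented CP. Its other measured probe set in NCI-H358, 227253_at, had log2 1.332 there (signal 21.83 and 54.95) and 1.005 in A549. The size of the CP difference in NCI-H358 was therefore not settled. Higher in both lines as well were LINC00261, a noncoding RNA (0.63 and 0.69), ZNF835 (0.59 and 0.62), MEX3A, an RNA-binding protein (0.58 and 0.56), CRAT, carnitine acetyltransferase (0.45 and 0.70), CDKN1C, a cyclin-dependent kinase inhibitor (0.49 and 0.53), KIF25-AS1 (0.44 and 0.76), CASC15 (0.48 and 0.40) and RASL11B (0.39 and 0.46). Lower in both lines were CLDN3, a tight junction claudin (-0.63 and -0.59), TNRC6C, a factor of microRNA silencing (-0.61 and -0.54), MYO15B (-0.49 and -0.64), ICAM2, an intercellular adhesion molecule (-0.90, bounded by the floor, and -0.39), RELT, a TNF receptor family member (-0.42 and -0.44), SNAPC4, a factor of small nuclear RNA transcription (-0.46 and -0.41), and TTR, transthyretin (-0.40 and -0.36). None of these passed the test over all genes: limma called 0 of 12273 genes at an adjusted p of 0.05, with 372 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and eBayes with a trend called 0, with 329. The 372 and the 329 were each a smaller share of the genes than the 0.05 expected if no gene differed. For CHST11 the limma unadjusted p was 0.000638, for CP 0.0039 and for CLDN3 0.00143. On simulated data the same fit called 99.7% of 200 genes that changed by log2 2, but 68.5% when only 5 genes did. Some other probe sets of these genes had the opposite sign: CLDN3 at 0.05 in NCI-H358, CRAT at -0.19 in A549 and -0.18 in NCI-H358, MEX3A at -0.13 in NCI-H358 and SNAPC4 at 0.10 in A549. With the median of probe sets CLDN3 had -0.32 and -0.27, MYO15B -0.08 and -0.05, CRAT 0.13 and 0.26, and in A549 MEX3A had 0.20, SNAPC4 -0.18 and ICAM2 -0.47.

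Of the genes at least 2-fold apart, 6 of 13 in A549 and 2 of 6 in NCI-H358 were measured in both lines. BIK had a log2 ratio of 1.45 in A549 and 0.16 in NCI-H358, C1R 1.13 and 0.00, CEMIP -1.36 and 0.56, and SYNE2 -1.05 and 0.36. CEACAM6, SPINK6, GDA, CA2, COL4A4, CST1 and C4BPB were below the floor on both NCI-H358 arrays, so their response there could not be judged. At least 2-fold higher in both lines, by the probe set representing each gene, was 1 gene, CHST11, where independent lists would share 0.000757. CHST11 was the gene of the vector, so its place in both lists is no test of a shared response. With CHST11 left out after the overlap was seen, 0 genes were at least 2-fold higher in both lines. That 0 were lower in both was fixed beforehand, since NCI-H358 had 0 genes at least 2-fold lower. At 1.5-fold, LINC00261 and ZNF835 were higher in both lines beside CHST11. Without CHST11, left out after the overlap was seen, these 2 stood against 0.154 for independent lists and a mean of 0.248 in shuffles matched on signal, 2.7% of which gave 2 or more. CLDN3 alone was lower in both at 1.5-fold, against 0.119 and a shuffle mean of 0.211, reached in 19.4% of shuffles. In opposite directions, 3 genes differed at least 1.5-fold, ADGRL3, NPNT and ZBTB20. Across the 10572 genes measured in both lines, which are not independent replicates, the ratios had r = -0.091 and rho = -0.087, and 47.7% had the same sign.

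Among genes named in advance whatever their values, TFRC, the transferrin receptor, had log2 ratios of -0.19 in A549 and 0.15 in NCI-H358, FTL, the ferritin light chain, -0.01 and -0.10, and SLC40A1, the iron exporter ferroportin, 0.02 and 0.19. E-cadherin (CDH1) had 0.04 and 0.28, vimentin (VIM) 0.01 and -0.38, the hyaluronan receptor CD44 -0.02 and -0.08, and the chondroitin sulfate proteoglycan VCAN -0.32 and -0.05. The 8 CD44 probe sets ran from -0.22 to 0.33 in A549, and the 5 of VCAN from -0.05 to 0.38 in NCI-H358. With the median of probe sets CD44 in A549 had 0.26 and VCAN in NCI-H358 0.30, so neither of these signs was settled. In NCI-H358 all 8 measured CD44 probe sets lay below 0, from -0.306 to -0.076. The 3 TFRC probe sets ran from -0.19 to 0.16 in A549. All 5 VCAN probe sets lay between -0.371 and -0.236 in A549, the pair of arrays in which the long mRNA list had its median of -0.474. VCAN was not on that list and mRNA lengths were not used here, so its low ratio was not separated from that shift. VCAN and TFRC in A549 and VIM, CDH1 and SLC40A1 in NCI-H358 lay beyond the probe set SD of their line. The SD over all genes was 0.18 in A549 and 0.195 in NCI-H358, so a ratio just beyond it was ordinary.

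The gene lists fixed in advance differed little in A549. The median of the 25 measured genes of chondroitin and dermatan sulfate synthesis, CHST11 not included, was 0.078, higher than 97.97% of random lists, with 20 genes above 0. Its chain-initiating enzymes CSGALNACT1 (0.41) and CSGALNACT2 (0.24) were among the highest and the polymerising factor CHPF (-0.44) the lowest. Proliferation genes had a median of 0.042 (percentile 97.84, 25 of 38 above 0), with TTK at 0.18 and MKI67, of the long mRNA list, at -0.61, and unfolded protein and amino acid stress genes 0.049 (percentile 97.74, 21 of 30 above 0), with XBP1 at 0.11. Below most random lists lay matrix proteolysis and adhesion (-0.069, percentile 0.24, 18 of 24 below 0), with LAMB3 at -0.45, and epithelial junction genes (-0.062, percentile 0.84, 13 of 20 below 0), with EPCAM at -0.77 and DSP at -0.34. Lung epithelial differentiation lay at -0.089 (percentile 2.06, 12 of 17 below 0), with TFF1, a secreted trefoil factor, at -0.84 and the mucin MUC5B, of the long mRNA list, at -0.65. These lists moved in the pair of arrays in which the long mRNA list had its median of -0.474. Under cyclic loess normalization the percentiles of the 3 higher lists were 96.75, 96.54 and 96.89 and that of the lung list 3.51, all inside the central 95%, and without the long mRNA and mitochondrial genes the lung list was at 3.05. Also inside were the proliferation and stress lists under quantile normalization (96.5 and 97.32), and these and the lung list with the median of probe sets (89.77, 90.63 and 15.23). With the filter at the 75th percentile the chondroitin, stress, epithelial junction and lung lists were at 97.1, 96.23, 2.71 and 25.75. With no filter the stress, epithelial junction and lung lists were at 97.3, 6.56 and 49.91, so of the 6 only matrix proteolysis stayed outside under each setting.

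In NCI-H358, genes of cholesterol synthesis and uptake had the highest standing, with a median of 0.181 at percentile 100 of 10000 random lists and 18 of 22 genes above 0. INSIG1, a sterol-regulated retention protein, had a log2 ratio of 0.74 and TM7SF2, a sterol reductase, 0.62, while the fatty acid desaturase FADS2 had -0.69. TGF-beta, BMP, Wnt and Hippo targets had a median of 0.19 (percentile 99.98, 11 of 17 above 0), with AXIN2 at 0.33 and TGFB2 at 0.27 but TGFB1 at -0.53. Hypoxia and glycolysis genes had 0.114 (percentile 99.84, 21 of 28 above 0), with BNIP3L at 0.43 and VEGFA at 0.19, mesenchymal transition genes 0.138 (percentile 99.54, 10 of 16 above 0), with LOX at 0.53 and VIM at -0.38, and lung epithelial differentiation genes 0.114 (percentile 98.02, 14 of 16 above 0), with ABCA3 at 1.03. Cytokines and NF-kB targets lay low, with a median of -0.148 (percentile 0.01, 16 of 24 below 0), IL1B at -0.35 and RELB at -0.38, although CXCL8 had 0.37. Of the 3 measured leukocyte markers, 2 lay below 0 in this line and CORO1A had 0.00 (median -0.35). Some of the genes named here varied between probe sets in this line. VEGFA ran from -0.688 to 0.202 over 4 measured probe sets, BNIP3L from 0.069 to 0.434 over 2, and IL1B from -0.345 to 0.078 over 2. In this line the long mRNA list stood at 0.127, above 0. The hypoxia list was at percentile 92.84 with the median of probe sets, the mesenchymal list at 70.11 and the lung list at 92.48 with the stricter filter, and the TGF-beta and mesenchymal lists at 48.57 and 50.27 with no filter, where unmeasured genes sit at the floor.

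**Figure D3:**
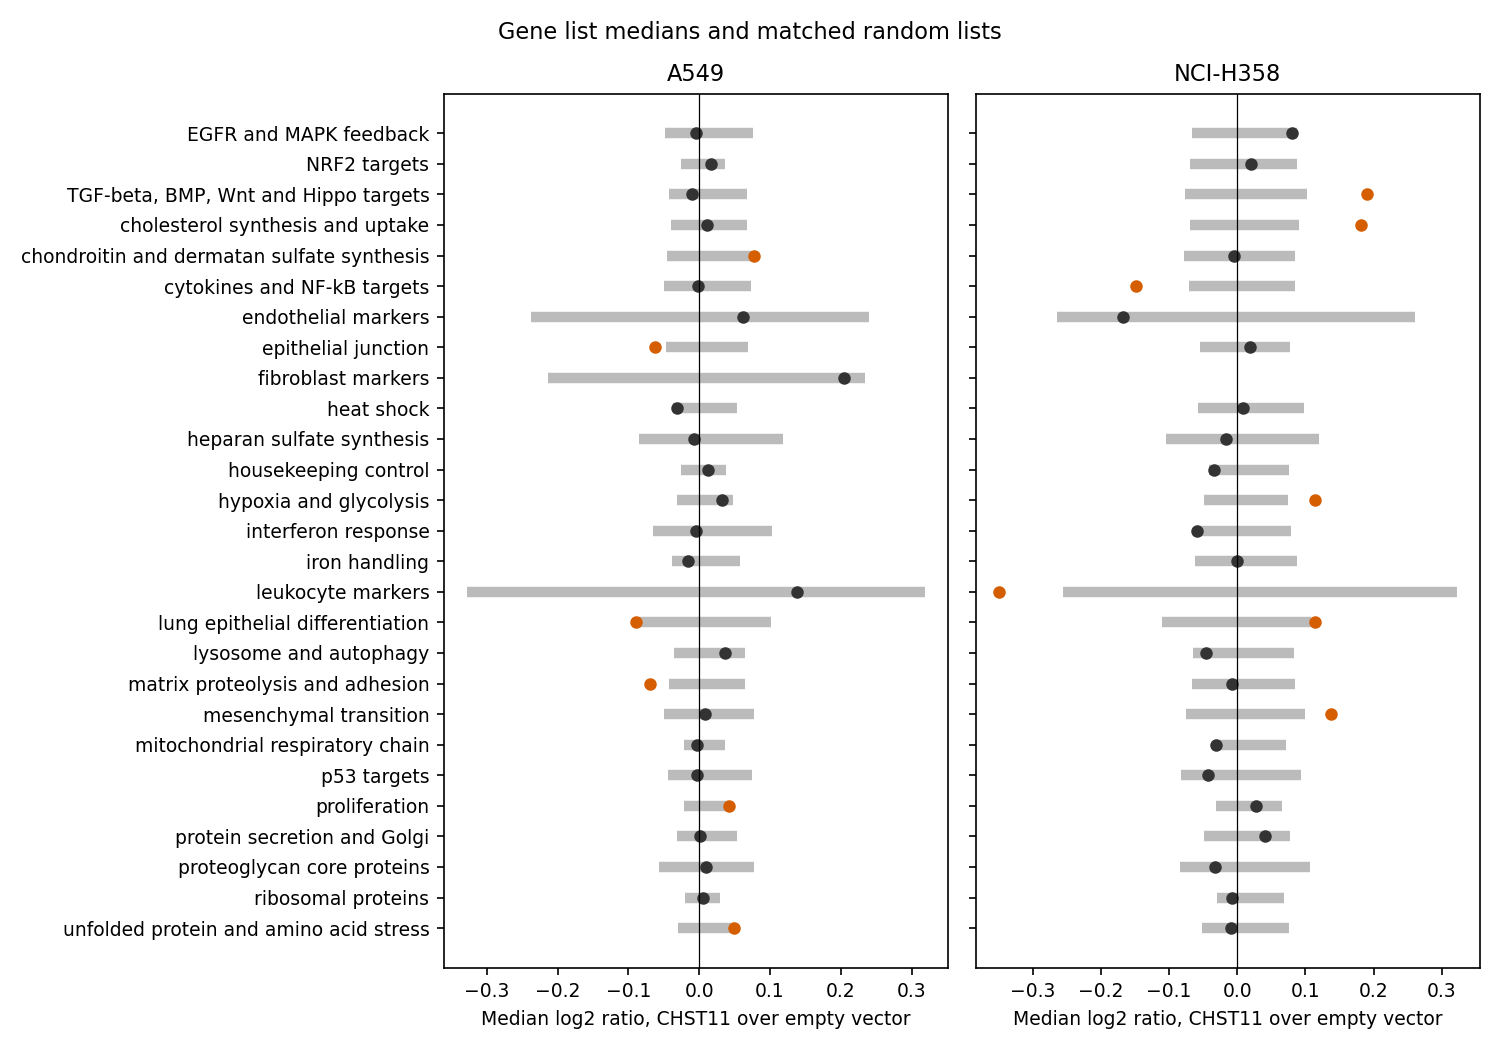
Median log2 ratio of CHST11 over empty vector of each fixed gene list in A549 (left) and NCI-H358 (right); grey bars span the central 95% of 10000 random lists matched in size and signal, and orange points lie outside them. In all, 13 of 53 medians lay outside. Lists of independently varying genes would give 2.65, but genes of a fixed list may vary together, and lists of a line share arrays. The number to be had without a vector effect is therefore not known, and the excess over 2.65 was not tested. By percentile, cholesterol synthesis (0.181) was highest and cytokines (-0.148) lowest, both in NCI-H358.

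Apart from the markers of other cell types, the remaining lists lay inside the central 95% in A549 and NCI-H358. Iron handling genes had medians of -0.016 and 0.0 even with CP in the list, interferon response genes -0.005 and -0.059, and EGFR and MAPK feedback genes -0.004 and 0.08. Proteoglycan core proteins had 0.009 and -0.032, with HSPG2, perlecan, a member of the long mRNA list, at -0.75 and -0.11, and heparan sulfate synthesis -0.008 and -0.017. The values were 0.017 and 0.02 for NRF2 targets, -0.003 and -0.043 for p53 targets, -0.031 and 0.008 for heat shock, 0.036 and -0.046 for lysosome and autophagy, and 0.001 and 0.041 for protein secretion and Golgi. Ribosomal proteins had 0.005 and -0.007, the mitochondrial respiratory chain genes of the nucleus -0.003 and -0.031, and housekeeping controls 0.013 and -0.034. For lists outside the range in 1 line, the other line gave -0.005 for chondroitin sulfate synthesis, 0.027 for proliferation, -0.009 for unfolded protein stress, -0.007 for matrix proteolysis and 0.019 for epithelial junction in NCI-H358, and 0.011 for cholesterol synthesis, -0.01 for TGF-beta, BMP, Wnt and Hippo targets, 0.032 for hypoxia, 0.008 for mesenchymal transition and -0.002 for cytokines in A549. In the shared limma fit, 1 gene passed when adjusted over the list alone, against 0 over all genes tested. It was CLDN3 among epithelial junction genes (limma, adjusted p = 0.0399). CLDN3 was lower in both lines by its representing probe set, while its other measured probe set had 0.048 in NCI-H358. Each of the 27 lists was adjusted separately, with no correction across lists, so this call is weak. CP in the iron list had an adjusted p of 0.0936 in the same limma fit.

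The cell lines themselves differed in many genes. In the limma fit, 7909 of 12273 genes differed at an adjusted p of 0.05, 4157 higher and 3752 lower in NCI-H358, but 1905 of 19775 did with no filter, where unmeasured genes sit at the floor. Higher in NCI-H358 were EDIL3, an integrin-binding matrix protein (at least 92.1-fold), CTHRC1, a secreted collagen repeat protein (at least 76.0-fold), RAC2, a small GTPase (at least 63.0-fold), MAL2 (at least 61.0-fold), CDH3, P-cadherin (at least 59.9-fold), and TNC, tenascin C (at least 41.6-fold). Lower were ALDH1A1, a retinaldehyde dehydrogenase (at least 417-fold), AKR1B10 (at least 401-fold), AKR1C2 (197-fold), AKR1C3 (183-fold), the neuropeptide precursor NTS (at least 175-fold), the chemokine CXCL5 (at least 133-fold), CA12 (at least 123-fold), GPX2, a glutathione peroxidase (at least 121-fold), and GJA1, a gap junction protein (at least 82.1-fold). Folds given as at least were taken against the filter signal of 27 where the dimmer line lay under it. All 24 measured NRF2 targets, among them AKR1B10, AKR1C1 (122-fold) and ALDH3A1 (46.4-fold), were lower in NCI-H358, with a median of -1.85. Of 33 interferon response genes, 28 were higher, 2 lower and 3 not past the threshold, with IFITM1 at least 2.72-fold, PSMB9 3.36-fold and MX1 at least 1.51-fold higher. Of 22 p53 targets, 15 were lower, 2 higher and 5 not past the threshold, with CDKN1A 2.39-fold and TP53I3 2.24-fold lower, and of 28 epithelial junction genes, 17 were higher and 5 lower, with EPCAM 31.9-fold and CDH1 4.69-fold higher. VIM was 2.09-fold and CD44 3.98-fold lower in NCI-H358. Of 25 ribosomal proteins, 17 were not past the threshold. Each line was represented by its 2 vector arrays. The p-values rested on the difference between the lines in their response to the vector, not on a spread between cultures of a line.

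Control probe sets gave the quality of the RNA. The 3' over 5' signal ratio of GAPDH was 2.64, 2.14, 2.14 and 2.19 in A549 empty vector, A549 CHST11, NCI-H358 empty vector and NCI-H358 CHST11, and that of ACTB was 2.4, 2.14, 2.06 and 2.32. The 9 spike-in control probe sets had a median log2 ratio of 0.084 in A549 and 0.089 in NCI-H358. Of 12 fibroblast markers, COL1A1 and FBLN1 were above the filter on each array and THY1 on both A549 arrays, with a list median of 0.204 in A549 and too few genes in NCI-H358. Of 12 endothelial markers, EGFL7, ENG and PECAM1 were above the filter on each array, with list medians of 0.062 and -0.167, inside the random range. Leukocyte markers rested on 3 genes per line, with medians of 0.138 and -0.35. The latter stood at percentile 0.615 of random lists (50.12 with no filter), with LAPTM5 at -0.38, CORO1A at 0.00 and a highest signal of 83.6.

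**Figure D4:**
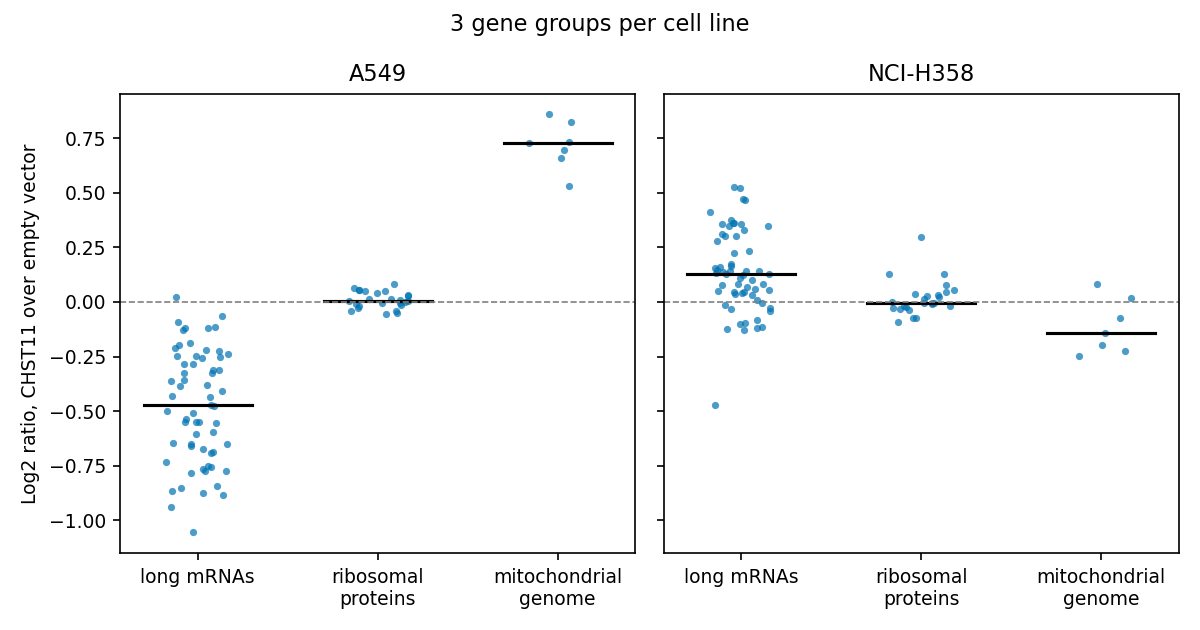
Log2 ratio of CHST11 over empty vector for each measured gene of 3 groups in A549 (left) and NCI-H358 (right), with black bars at the medians. In A549 the long mRNAs (median -0.474) and the genes of the mitochondrial genome (0.73) lay on opposite sides of the ribosomal proteins (0.005); in NCI-H358 the medians were 0.127, -0.14 and -0.007.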

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

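The tests of RNA degradation, of an effect common to both lines, of size-dependent recovery, of the transgene's extent, and of CP in NCI-H358 were chosen only after the result was seen; those of scaling and of single probe set scatter were set out before.

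Several values were singled out because they had opposite signs in the cell lines; these differences were not tested, since each line had 1 array per vector. ADGRL3, an adhesion receptor, had a log2 ratio of -0.614 in A549 and 0.753 in NCI-H358. NPNT, nephronectin of the extracellular matrix, had -0.644 and 0.714, and ZBTB20, a zinc finger repressor, -0.872 and 0.781. All 5 measured ZBTB20 probe sets lay below 0 in A549 and above 0 in NCI-H358. ADGRL3, NPNT and ZBTB20 all went in the direction of the long mRNA list, which had medians of -0.474 in A549 and 0.127 in NCI-H358. Their ratios were not separated from that shift. The lung epithelial differentiation list had medians of -0.089 and 0.114. Probe sets without a single gene symbol, used in no comparison, differed at least 2-fold in 2 cases in A549, both lower with CHST11, and in 2 in NCI-H358, both higher.

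In A549 the listed long mRNAs had a median log2 ratio of -0.474 and the genes of the mitochondrial genome 0.73, while NCI-H358 gave 0.127 and -0.14. Degraded RNA in the A549 CHST11 sample needed a rise in the 3' over 5' log2 ratios of GAPDH and ACTB. Their mean change was -0.235, which argued against it for these 2 control genes. The A549 arrays did differ in this measure, with higher ratios on the empty vector array (2.64 against 2.14 for GAPDH, 2.4 against 2.14 for ACTB). These controls cannot show a loss limited to long mRNAs. Signal-dependent scaling was argued against too, because the long mRNAs not seen before listing stayed at -0.396 after cyclic loess normalization, and an effect of CHST11 common to both lines by their median of 0.134 in NCI-H358. Size-dependent recovery or labelling of RNA in 1 of the A549 samples may account for the median of -0.379 of these genes in A549. With 1 array per group it cannot be told apart from an effect of CHST11 in A549.

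Of the 3 CHST11 probe sets, 1 was higher with the CHST11 vector. Scatter of a single probe set was argued against, because 0 of 1787 other genes with at least 3 probe sets had a gap as large in both lines. The vector might carry a transcript without the part that the other 2 probe sets read; their mean log2 ratio over both lines was 0.012, but their positions were not used here, so this stays open.

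CP was higher with the CHST11 vector in both lines. Scatter of a single probe set was argued against by 0 of 2032 other genes with at least 3 probe sets in A549 whose lowest ratio reached that of CP, the next being RARRES1 at 0.296. The RNA difference that moves the long mRNAs would put CP below 0 in NCI-H358, where it had 0.532, and 2.11% of 569 genes of like signal lay as high there. A response of CP to CHST11 is therefore a hypothesis that these tables leave standing, without a replicate in either line, and a difference between the transduced cultures stays untested.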

How the results depend on the processing

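The run without the long mRNA and mitochondrial genes was chosen only after the result was seen. Within each line, the 2-fold counts lay between 12 and 14 in A549 and between 6 and 9 in NCI-H358 under the settings not named next. With the 75th percentile filter, which tests fewer genes, they were 5 and 3, and with 1.5-fold, a wider rule by construction, 138 and 133; with the median of probe sets NCI-H358 had 3, and the cause was not tested beyond CHST11. The median of probe sets, taken on each array, gave CHST11 0.231 in A549 and 0.140 in NCI-H358. In A549 it set 219634_at on the empty vector array (129.0) against 226372_at on the CHST11 array (151.4), so 0.231 is no ratio of a probe set; in NCI-H358 both medians were 226372_at. Shared 2-fold genes numbered 0 with that choice, 0 without CHST11, left out after seeing the data, and 4 at 1.5-fold. The correlation of ratios was -0.156 with the 75th percentile filter and -0.067 with no filter; it stayed below 0 under all settings. Shared genes by limma numbered 0 under each setting, with 1 (no block) to 1222 (no filter) at an unadjusted p under 0.05. The cell line difference covered 1905 genes with no filter and 6507 to 8333 otherwise. Lists outside the random range numbered in A549 2 with cyclic loess, 3 with the 75th percentile filter and 3 with no filter, and in NCI-H358 4 with the stricter filter and 4 with no filter; apart from the gene choice, the cause was not tested. Without the long mRNA and mitochondrial genes the counts were 12 and 6 and the correlation -0.078. No 2-fold vector ratio of a gene named by the rule reversed its sign; single genes of the cell line difference were not recomputed. Leaving out 1 cell line leaves a ratio with no test, so no count could be given. Signals near the floor of 16.14 limit folds of dim genes to lower bounds.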

Other observations

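The gene groups in this part were chosen only after the result was seen.

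Zinc finger genes lay slightly high with CHST11 in NCI-H358: the median log2 ratio of 362 measured genes with ZNF symbols was 0.047, at percentile 100 of 10000 random lists, and 11 of them were at least 1.5-fold higher and 0 lower. In A549 the 291 measured members had 0.021, at percentile 67.56. Replication-dependent histone genes had a median of 0.128 in NCI-H358 (percentile 98.76, 12 of 14 above 0) and 0.014 in A549 (percentile 48.43; -0.007 under quantile normalization). With the filter at the 75th percentile the NCI-H358 percentiles were 91.11 for zinc finger and 92.09 for histone genes, inside the central 95%, and with no filter 99.99 and 94.86. The genes of the mitochondrial genome, which encode respiratory chain subunits, were above 0 in A549 in 7 of 7 cases, while the 28 measured respiratory chain genes of the nucleus had a median of -0.003 there.

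Across genes, which are not independent replicates, the log2 ratio ran against the genomic span of the gene in A549 (rho = -0.165, 11443 genes) and with it in NCI-H358 (rho = 0.223, 11389 genes). Genomic span includes introns and is not the length of the mRNA.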
